A study of Mus musculus with 6 samples.

How the data were processed

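Gene expression was measured on 6 Affymetrix mouse GeneChip arrays, hybridized with biotin-labelled material made from total RNA of L-DKO mice. The series title describes these mice as having high levels of E proteins, transcription factors that act in lymphocyte development. Per the labels, 3 arrays held premalignant natural killer T (NKT) cells sorted from mice aged 3 weeks. Another 2 held lymphoma cells from Peyer's patches that bound the CD1d tetramer (CD1dtet+), from mice aged 20 and 18 weeks, and 1 held lymphoma cells from the thymus at 37 weeks that did not bind it (CD1dtet-). The tetramer marks T cells that carry the invariant NKT receptor. The series design gives 3 mice for the premalignant cells. That the tumors came from separate animals was read only from their different ages, so p-values measure the spread between these samples. Stage differed together with age, and among the tumors tetramer binding differed together with age and site. The tissue of the premalignant cells is not stated in the labels, so site was not excluded as a further difference between the stages.

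The authors deposited log2 values, 1 per probe set and array. RMA, which corrects background, normalizes quantiles and summarises probes, and limma are named per the submitters' processing notes, without versions or the order of steps. Filters and the probe set definition are not given in the sources used here. The values ran from 1.99 to 14.67, and array medians lay between 6.73 and 6.83. The number of arrays limits the precision. Dim probe sets lie near the bottom of this scale, where folds are approximate.

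The value table identifies its 22690 probe sets by Affymetrix ID, and the files do not pair these IDs with gene names. Each ID is printed after the letters ID, and no name was inferred from one, except for control probe sets whose IDs carry a transcript name. The planned tests used 1 probe set per gene, and 35 lists of genes and cell type markers had been fixed. Without gene names every probe set was tested singly, and none of the 35 lists was tested. A second deposited table has gene symbols and 9 value columns, none of which matched a sample label, and it was not used here.

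The 64 control probe sets were left out and 22626 probe sets were tested on the deposited log2 values without further normalization. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over 22626 probe sets and a threshold of 0.05 on the adjusted p. Lymphoma was compared with premalignant cells in a fit of 2 groups of 3 arrays. The other comparisons came from a fit of 3 groups, in which the single CD1dtet- tumor has no spread of its own and is assumed to vary like the other groups. Control transcripts were tested in fits that also held the control probe sets. Measures of single arrays were compared by exact permutation tests, two-sided, which cannot give a p below 0.1 with 3 arrays against 3. The tests, the alternatives and the rule for named items were fixed before the data were examined, with the exceptions given here.

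The rule for named items took the largest changes by fold among those past the threshold whose arrays did not overlap between the groups. It was written for 10 genes on each side in the first comparison and fewer in the others, with 8 genes always named, and was reduced to 2 rises and 2 falls per comparison because the IDs have no names. The analysis was tested on simulated arrays with 200 changed probe sets and the same spread in all groups. That spread came from the fit of 3 groups, which leaves out the difference between the tumor kinds. The fit of lymphoma against premalignant cells holds that difference as spread, so its recovery in the data may be lower than simulated. For lymphoma against premalignant cells, 80.6% of changes of 1 log2 unit and 97.0% of changes of 2 units were recovered among 22626 probe sets, with 11 false calls among 195. For the CD1dtet- tumor against the CD1dtet+ tumors, 17.9% and 89.6% were recovered, with 13 false calls among 151.

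Other analyses fixed at the same time were a repeated quantile normalization, median centring, leaving out the dimmest of 3 equal parts of the probe sets, an intensity trend with robust moderation, array weights, a 2-fold minimum, other sets of arrays in the fit, the replicate number as a block, and leaving out each array in turn. Spike-in levels as covariates, leaving out probe sets with the suffixes _x_at and _s_at, fits of the CD1dtet- tumor with only the CD1dtet+ or only the premalignant arrays, and all counts of overlap and of separated, gained or lost signal were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.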

Results

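Expression profiles were obtained from 3 samples of premalignant NKT cells and 3 lymphomas of L-DKO mice, 2 of them CD1dtet+ and 1 CD1dtet-. The premalignant samples resembled one another most. Their pairs correlated at r = 0.991 to 0.994 across the 22626 probe sets, and 0.371% to 1.10% of probe sets differed by 2-fold or more within a pair. The CD1dtet+ tumors correlated at 0.977 and differed by 2-fold or more at 5.56% of probe sets. The CD1dtet- tumor differed by as much from the CD1dtet+ tumors at 7.68% to 9.59% of probe sets, and the lymphomas differed from the premalignant samples at 8.66% to 9.60%. These correlations are across probe sets, which are not independent replicates. The median SD of a probe set was 0.14 log2 units over the premalignant samples and 0.20 over the lymphomas.

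**Figure D1:**
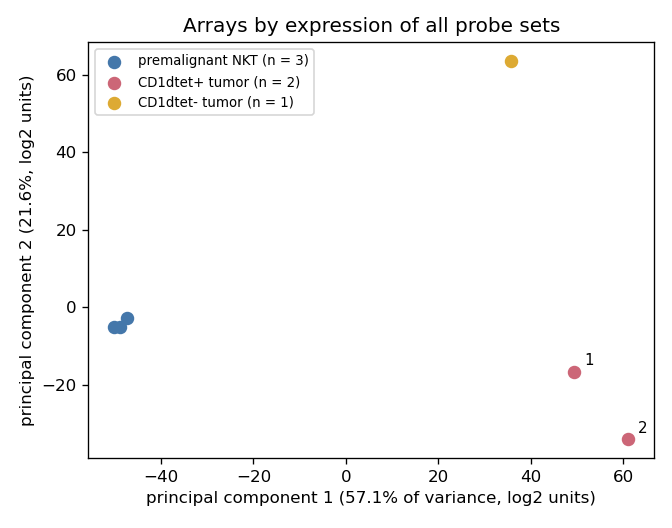
Scores of the 6 arrays on principal components 1 (horizontal, 57.1% of the variance) and 2 (vertical, 21.6%) of all tested probe sets in log2 units, 1 point per array, coloured by group, with numbers giving the CD1dtet+ tumor. The premalignant arrays lie between -50.1 and -47.4 on component 1 and the lymphomas between 35.8 and 61.1, with the CD1dtet- tumor at 63.5 on component 2.

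Transcripts named by the control probe sets were compared first, since their identity is carried by their IDs. For beta-actin, a cytoskeletal protein, the 3' probe set read 14.23 ± 0.04 (SD, n = 3) log2 units in lymphoma and 14.29 ± 0.02 (SD, n = 3) in premalignant cells. For Gapdh, an enzyme of glycolysis, the 3' probe set read 13.11 ± 0.07 (SD, n = 3) and 12.93 ± 0.05 (SD, n = 3), a difference of 0.19 with a 95% interval of -0.06 to 0.43, and the middle and 5' probe sets differed by 0.33 (interval -0.02 to 0.68) and 0.44 (interval -0.04 to 0.92). The transferrin receptor, which takes up iron, differed by 0.04 at its 3' probe set (interval -0.60 to 0.67), and pyruvate carboxylase, a mitochondrial enzyme, by -0.27 (interval -0.84 to 0.30). The probe sets for the middle, 5' and 3' parts of 18S ribosomal RNA differed by -0.65 (interval -1.20 to -0.10; limma adjusted p = 0.153), -0.36 (interval -1.15 to 0.43) and 0.29 (interval -0.54 to 1.12). Of the 19 control probe sets for mouse transcripts, 0 passed the threshold in each of the 4 comparisons with limma. At an unadjusted p under 0.05 there was 1 for lymphoma against premalignant cells, 1 for the CD1dtet- tumor against premalignant cells, and 0 in the other comparisons. Transcripts of this control set that missed the threshold are not shown to be equal.

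Measures of RNA quality and input were compared over the same arrays. The log2 difference between the 3' and 5' probe sets of Gapdh, which grows as RNA degrades, was 0.01 ± 0.11 (SD, n = 3) in lymphoma and 0.26 ± 0.30 (SD, n = 3) in premalignant samples (exact permutation test, two-sided, p = 0.3). Poly-A spike-ins, added to the RNA before labelling, averaged 8.19 ± 0.75 (SD, n = 3) and 8.72 ± 0.74 (SD, n = 3) log2 units (exact permutation p = 0.5). Hybridization spike-ins averaged 10.64 ± 0.24 (SD, n = 3) and 11.18 ± 0.29 (SD, n = 3) (exact permutation p = 0.2). Array medians were 6.79 ± 0.03 (SD, n = 3) in lymphoma and 6.74 ± 0.01 (SD, n = 3) in premalignant samples without overlap (exact permutation p = 0.1). Over the 6 measures compared, Benjamini-Hochberg adjusted values were 0.6 for these exact tests, and the smallest p that 3 arrays against 3 can give is 0.1.

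Lymphoma cells were compared with premalignant NKT cells of the same strain to describe how expression differed between these stages. The largest rises ran from the bottom of the scale in premalignant cells to bright signal in all 3 tumors, and the largest falls ran the other way. Probe set ID-1439426_x_at averaged 12.65 ± 0.36 (SD, n = 3) log2 units in lymphoma and 3.32 ± 0.91 (SD, n = 3) in premalignant cells, a rise of 9.33 ± 0.46 (SE; limma adjusted p = 0.000478). Probe set ID-1452417_x_at rose by 9.02 ± 0.24 (SE), from 3.99 ± 0.44 (SD, n = 3) to 13.01 ± 0.23 (SD, n = 3), with limma adjusted p = 8.25e-05. Probe set ID-1427752_a_at fell by 6.68 on the log2 scale, from 10.59 ± 0.29 (SD, n = 3) to 3.91 ± 0.25 (SD, n = 3), with a standard error of 0.20 (limma adjusted p = 9.02e-05). Probe set ID-1450680_at fell by 6.31, from 9.17 ± 0.50 (SD, n = 3) to 2.86 ± 0.30 (SD, n = 3), with a standard error of 0.28 (limma adjusted p = 0.000372). The files do not pair these IDs with gene names, and the suffix _x_at marks probe sets whose probes can match several transcripts. RNA of other cell types in the lymphoma samples was not excluded as a source of these rises.

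In all, 1048 of 22626 probe sets (4.63%) passed the threshold between lymphoma and premalignant cells, 582 higher and 466 lower in lymphoma (limma with Benjamini-Hochberg adjustment). With arrays centred on their medians, 567 were higher and 725 lower. Among the 1048, 456 were higher and 173 lower by 2-fold or more, and 134 higher and 26 lower by 8-fold or more. The count was 174, 167 and 285 without premalignant sample 1, 2 or 3, 530 without CD1dtet+ tumor 1, and 2184 without the CD1dtet- tumor. It was 328 with the poly-A and 47 with the hybridization spike-in level as a covariate, 2038 with array weights and 2285 with both tumor kinds weighted equally.

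Probe sets were also counted by their values on each array, with limits chosen after the data were seen. All lymphomas lay outside the range of all premalignant samples at 7436 probe sets (32.9%, where chance gives 10%), 2558 higher and 4878 lower in lymphoma. The median change over all probe sets was -0.09 log2 units. Such a small common shift can add to the lower count, so its excess is no measure of expression lost. At 431 the gap was 2-fold or more, with 361 higher and 70 lower in lymphoma, and this count was 751 without the CD1dtet- tumor. Signal under 5 log2 units in every premalignant sample and at 8 or more in every lymphoma was found at 20 probe sets, or 33 without the CD1dtet- tumor. The reverse was found at 2 probe sets, ID-1427752_a_at and ID-1450680_at, or at 5 without premalignant sample 1.

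**Figure D2:**
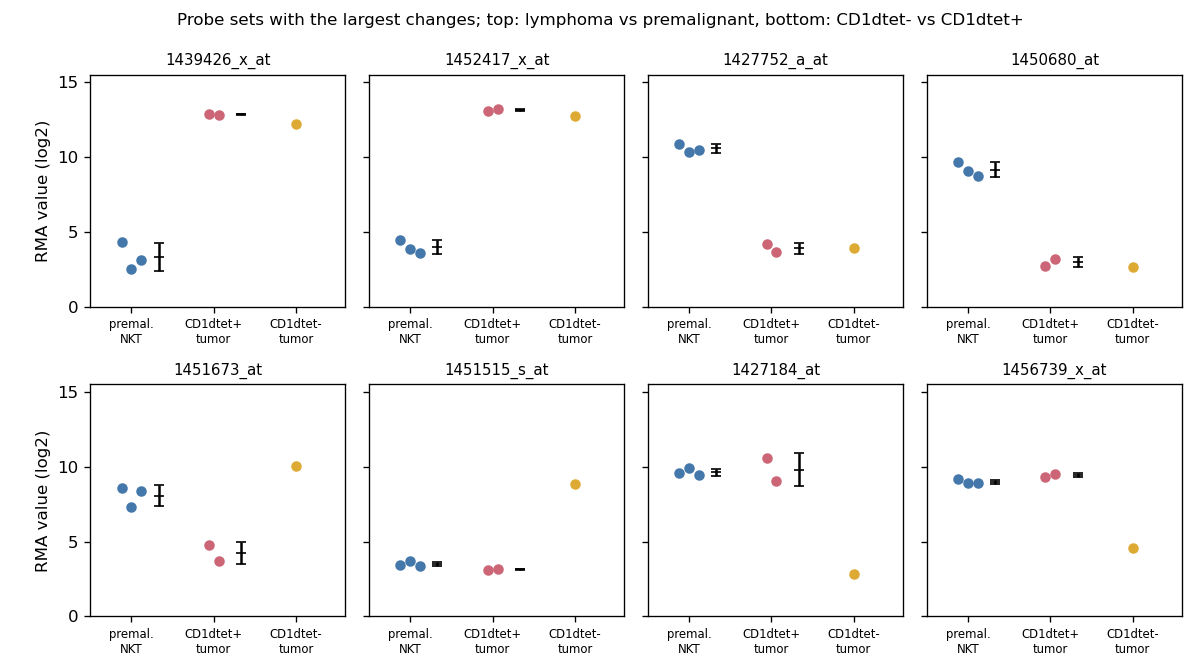
RMA values (log2, vertical axis) of named probe sets by group (horizontal axis), 1 point per array, with the mean and SD beside groups of more than 1 array. In the upper panels, for lymphoma against premalignant cells, all 3 tumors lie on the same side of the premalignant samples, and the lower panels show the CD1dtet- tumor against the CD1dtet+ tumors.

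The CD1dtet+ tumors, which bind the tetramer, were then compared alone with the premalignant cells. The rule named the same probe sets, which is no separate support, as all these arrays were also in the first comparison. Probe set ID-1439426_x_at rose by 9.54 ± 0.49 (SE; limma adjusted p = 0.000583), and ID-1452417_x_at rose by 9.15 ± 0.26 (SE; limma adjusted p = 9.62e-05). Probe set ID-1427752_a_at fell by 6.68 with a standard error of 0.23 (limma adjusted p = 0.000192), and ID-1450680_at fell by 6.20 with a standard error of 0.31 (limma adjusted p = 0.000553). In this comparison of 2 arrays with 3, 2184 probe sets passed, 1191 higher and 993 lower in the tumors, and 202 were higher and 31 lower by 8-fold or more. With median centring 1174 were higher and 1539 lower. The count was 512, 635 and 887 without premalignant sample 1, 2 or 3, 671 with the replicate number as a block and 258 with the hybridization spike-in level as a covariate. It rose on leaving out 1 CD1dtet+ tumor, when the spread comes from the premalignant samples alone.

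The CD1dtet- tumor was compared with the premalignant cells in the same model. Probe set ID-1439426_x_at read 12.24 in this tumor, a rise of 8.92 ± 0.63 (SE; limma adjusted p = 0.00238), which was 0.0548 with the hybridization spike-in level as a covariate and ranged from 0.00109 to 0.0548 over all alternatives. Probe set ID-1427184_at fell by 6.78 with a standard error of 0.55 (limma adjusted p = 0.00362), and ID-1427752_a_at fell by 6.68 with a standard error of 0.29 (limma adjusted p = 0.000611). Probe set ID-1419764_at read 12.99 in the CD1dtet- tumor, 8.01 and 12.78 in the CD1dtet+ tumors, and 4.17 ± 0.07 (SD, n = 3) in premalignant cells. Its rise of 8.83 ± 1.60 (SE) had a limma adjusted p of 0.0342, which was 0.115, 0.110 and 0.107 without premalignant sample 1, 2 or 3 and ranged from 5.15e-05 to 0.289 over all alternatives. A total of 1356 probe sets passed, 841 higher and 515 lower in the tumor. These p-values assume that CD1dtet- tumors vary as the other samples do, which 1 tumor cannot show. The count was 401, 404 and 584 without premalignant sample 1, 2 or 3, 2774 without either CD1dtet+ tumor, when the spread comes from the premalignant samples alone, 2968 with array weights and 150 with the hybridization covariate.

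Both tumor kinds were higher than premalignant cells at 401 probe sets and lower at 207, where independent lists of these sizes would share 44.3 and 22.6. Unchanged groups simulated against the same controls shared on average 0 higher and 0.05 lower calls over 20 simulations. As no probe set was changed in these, they cannot show how many calls the shared controls add to lists of these sizes. The log2 changes of the tumor kinds correlated at r = 0.635 across probe sets, against 0.316 in the simulations. Their covariance was 0.324 against a simulated 0.0182, a difference of 0.306. The simulated covariance already holds the random spread of the shared controls, as estimated by the fit. The 3 premalignant samples served both comparisons and are too few to split, so part of the excess in shared calls may come from the shared controls. The counts were 139 and 30 without premalignant sample 1, 134 and 40 without sample 2, 165 and 80 without sample 3, 699 and 319 without CD1dtet+ tumor 1, and 694 and 460 without CD1dtet+ tumor 2.

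The CD1dtet- tumor was last compared with the CD1dtet+ tumors. Probe set ID-1451515_s_at read 8.82 in the CD1dtet- tumor, 3.14 ± 0.05 (SD, n = 2) in the CD1dtet+ tumors and 3.39 to 3.67 in premalignant cells, a difference between tumor kinds of 5.67 ± 0.18 (SE; limma adjusted p = 0.000860). Probe set ID-1451673_at read 10.05 and 4.23 ± 0.72 (SD, n = 2) in the tumor kinds, a difference of 5.82 ± 0.62 (SE; limma adjusted p = 0.0147), with premalignant values of 7.28 to 8.57 between them. Its adjusted p was 0.0576 without premalignant sample 3 and ranged from 0.00431 to 0.263 over all alternatives. Probe set ID-1427184_at read 2.85 and 9.81 ± 1.08 (SD, n = 2), a difference of -6.96 ± 0.58 (SE; limma adjusted p = 0.00700), with 9.63 ± 0.25 (SD, n = 3) in premalignant cells. Probe set ID-1456739_x_at read 4.59 and 9.43 ± 0.14 (SD, n = 2), a difference of -4.83 ± 0.19 (SE; limma adjusted p = 0.000860), with premalignant values of 8.90 to 9.15.

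Between the tumor kinds 614 probe sets passed, 367 higher and 247 lower in the CD1dtet- tumor. Of these, 312 had passed against premalignant cells for the CD1dtet- tumor alone and 162 for the CD1dtet+ tumors alone. Another 44 had changed the same way in both kinds, 35 in opposite directions, and 61 had passed for neither kind. Independent lists of these sizes gave 64.0 opposite calls, more than the 35 seen. Both comparisons share their controls, which favours changes in the same direction, so this difference decides nothing. The simulations, which keep the shared controls, gave a mean of 0. They hold no changed probe sets, so this mean is no measure for the 35. The count of 614 was 112, 136 and 180 without premalignant sample 1, 2 or 3, 330 with the hybridization covariate, and 2034 (876 higher and 1158 lower) and 1367 without CD1dtet+ tumor 1 or 2. The 35 became 4, 5, 9, 110 and 87 in the order of these samples and tumors. Without a CD1dtet+ tumor, 1 tumor is set against 1 with the spread of the premalignant samples alone, which says nothing about the tumor kinds. With the spread taken from the 3 lymphoma arrays alone, 0 probe sets passed with limma, none of the named ones among them, and 2208 had an unadjusted p under 0.05.

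**Figure D3:**
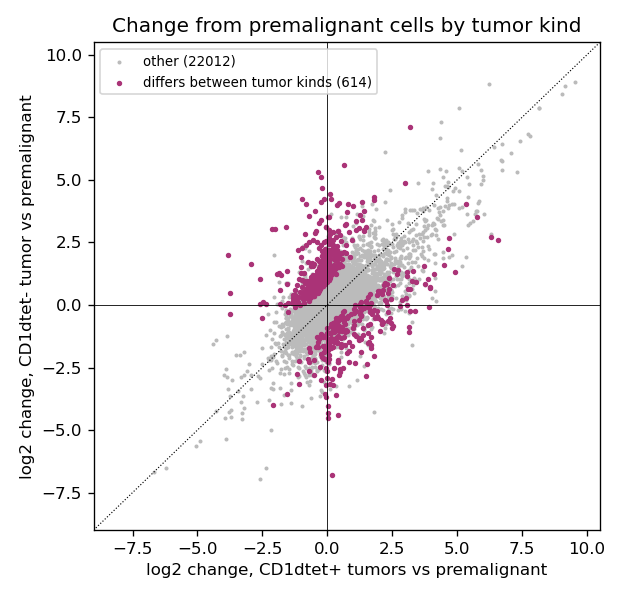
Log2 change from premalignant cells in the CD1dtet+ tumors (horizontal axis) and in the CD1dtet- tumor (vertical axis), 1 point per probe set, with a dotted line at equal change. The 614 probe sets that passed the test between tumor kinds are coloured and lie on both sides of that line.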

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

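The counts of 1048 and 614 were planned and all other tests here were chosen after these were seen; those of the spike-ins, of cross-hybridising probe sets and of the spread between tumors were chosen before their own results, and those of opposite directions, of signal gained and of other splits, the simulations of the tumor spread and the random covariates after.

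Lymphoma and premalignant arrays differed at 1048 probe sets, and the highest of the other splits of the 6 arrays into 3 and 3 gave 1. Each other split mixes the stages in both groups, so a difference between stages becomes spread there and lowers its calls. With 1 of 10 splits as large, the real one, the splits are also too few for a share under 0.05. For cross-hybridising probe sets, the share called among _at and _a_at probe sets was 0.752 of that among _x_at and _s_at (bootstrap interval 0.646 to 0.877). The bound set beforehand for this cause, under 0.5, was not met. The bound against it was nearly fixed, as _at and _a_at are 86.8% of all, and resting on this ratio was decided afterwards. The interval also treats probe sets as independent. The calls were not confined to _x_at and _s_at, since 872 were _at or _a_at probe sets (4.44% of that class, against 5.90%). Whether cross-hybridization accounts for part of the calls stays open. Unequal input and hybridization stay open: 0 probe sets followed the poly-A or the hybridization level past the limma threshold, with 927 and 893 at an unadjusted p under 0.05 where random covariates gave a median of 969, so the ratios of the changes with these covariates, 0.987 (0.982 to 0.991) and 0.972 (0.958 to 0.990), decide nothing. The calls did not hold with them: the median change was 1.20 with a median standard error of 0.18, then 1.19 with 0.19 and 328 calls under poly-A, and 1.15 with 0.28 and 47 calls under hybridization, which uses a residual degree of freedom and follows stage (correlation -0.78). RNA of other cell types stays open for the 20 probe sets that gained signal, among them the named rises ID-1439426_x_at and ID-1452417_x_at. No marker could be looked up without gene names, and age and site stay open as untested.

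The change from premalignant cells differed between the single CD1dtet- tumor and the CD1dtet+ tumors at 614 probe sets by a test of the difference. At 35 of them the changes were opposite in direction, fewer than the 64.0 opposite calls of independent lists. The shared controls favour changes in the same direction, so this count of independent lists decides nothing. Simulations without change, with the same shared controls, gave a mean of 0. They hold no changed probe sets, so this mean decides nothing. Unequal input stays open, since 0 probe sets followed poly-A past the limma threshold in this fit (1767 at an unadjusted p under 0.05, which 24 of 100 random covariates reached), and the ratio of 1.002 (1.001 to 1.004) with 552 calls decides nothing. The 1 pair of CD1dtet+ tumors differed by 2-fold or more at 5.56% of probe sets, against 0.371% to 1.10% for pairs of premalignant samples. Their median SD, over 2 arrays, was 0.15 log2 units, against 0.14 over 3 premalignant samples. An SD over 2 arrays tends to fall lower than an SD over 3, so these medians do not show an equal spread. The 90th percentiles of the SD were 0.52 and 0.30. Whether a larger spread between tumors accounts for the 614 calls stays open. On the 3 lymphoma arrays alone the median standard error was 0.23 against 0.21, with total degrees of freedom of 3.37 against 5.98. This fit gave 2208 probe sets at an unadjusted p under 0.05, all 614 among them, and 0 calls by limma. That count met the bound set beforehand for such a spread, but in simulations with 1 spread for all groups and a median of 546 calls it fell under 0.5 of the calls in 97 of 100 and to 0 in 48, and in an earlier set with a median of 2965 calls, far more than in the data, in 0 of 20 (median ratio 0.881), so it decides nothing. Tetramer binding, site, age and the individual tumor stay open as untested, since there was 1 CD1dtet- tumor.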

How the results depend on the processing

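The spike-in covariates, the fits without _x_at and _s_at probe sets, those of the CD1dtet- tumor with only 1 of the other groups, and the counts of overlap and of separated, gained or lost signal were chosen after the data were seen. Of 63 alternative counts of probe sets past the threshold, 32 were within 1.5 times the reported one, and 0 of the reported calls changed sign in any of them. Many alternatives keep the group means, so no sign could change in them. Some repeat a fit: the 2184 for the CD1dtet+ tumors is the same without the CD1dtet- tumor, which adds no spread. For lymphoma against premalignant cells (1048) the others were 2038 with array weights, 629 with a 2-fold minimum, 2285 with both tumor kinds weighted equally, 328 with the poly-A and 47 with the hybridization covariate, and 167 to 2184 leaving out single arrays. For CD1dtet+ tumors against premalignant cells (2184) they were 1182 with the 2-fold minimum, 258 with the hybridization covariate and 512 to 2827 leaving out single arrays. With the replicate block the count was 671; the samples share only a number, and differences between samples 1 and 2 of these groups correlated at -0.0027 across probe sets. For the CD1dtet- tumor against premalignant cells (1356) they were 2968 with array weights, 150 with the hybridization covariate, 2774 without the CD1dtet+ arrays and 401 to 2774 leaving out single arrays. For CD1dtet- against CD1dtet+ tumors (614) they were 330 with the hybridization covariate, 0 on the 3 lymphoma arrays alone with limma (2208 at an unadjusted p under 0.05) and 112 to 2034 leaving out single arrays. Leaving out a premalignant array lowered each of these 4 counts. Fewer arrays and degrees of freedom need not be the whole cause. For CD1dtet+ tumors against premalignant cells, leaving out a tumor costs as many and raised the count. The spread then comes from the premalignant samples alone. The cause was not tested. Of 244 alternative values of named probe sets, 232 stayed past the threshold, 12 did not and 0 reversed. Many of these also keep the group means, so they could not reverse. Of 45 other alternative counts, of overlap and of separated, gained or lost signal, 18 moved by more than 1.5 times, all on leaving out an array. Without the CD1dtet- tumor its own comparisons have no value. Not run for want of gene names or matching columns were the mean of the probe sets of a gene, the count of genes from single probe sets, the gene list tests by camera and fry, and the second deposited table.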

Other observations

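Both observations in this part were made in the data first and their tests chosen afterwards. Signal gained was seen in each tumor kind. The 20 probe sets under 5 log2 units in every premalignant sample and at 8 or more in every lymphoma had a median of 9.38 in lymphoma and 4.05 in premalignant cells. By the same limits 33 probe sets gained and 2 lost signal in the CD1dtet+ tumors, and 41 gained and 9 lost signal in the single CD1dtet- tumor, where fewer arrays have to pass.

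The largest rises held many probe sets of 1 class. Of the 20 largest rises that passed between lymphoma and premalignant cells, 11 had the suffix _x_at, against 6.68% of all tested (Fisher's exact test, two-sided, odds ratio 17.2, interval 6.46 to 47.0, p = 1.1e-08), and of the 20 largest falls 4 did. Probe sets of this class can read the same or related transcripts, so the test counts as independent some that need not be. The class as a whole passed the threshold at 5.89%, against 5.92% for _s_at and 4.47% for _at probe sets. Of all 582 rises that passed, 66 had the suffix _x_at.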
